A study of Mus musculus with 6 samples.

How the data were processed

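The series measured gene expression in the left atrium of adult male C57BL/6J mice, with 3 Sham and 3 MR libraries, each from its own mouse and labelled biological replicates. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, libraries were made with a stranded mRNA kit and sequenced as paired ends on a NovaSeq instrument. The submitters' processing notes name fastp, FastQC, MultiQC, HISAT2 2.1.0, SAMtools, featureCounts of Subread 2.0.1 and DESeq2 together with the mouse build GRCm39, without giving their order or settings. The annotation release and the strand setting of the counting are not given in the sources used here, so that reads of overlapping or antisense genes cannot be told apart with certainty.

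The deposited table has 55471 genes and, per the file headers, counts per gene and library. They were taken as not normalized because they are whole numbers with differing library totals. It also holds TPM values (counts scaled by gene length and library) made by the authors from these counts, per the file headers, and each TPM column sums to 1000000; they were read but gave no printed value. A log2 fold change of MR against Sham and a p-value with its adjusted p-value were deposited by the authors too, per the file headers; the tool and any shrinkage behind these columns are not given in the sources used here, and they are quoted only as the authors' values. Every column of per-sample values was matched to a library, so 0 were left unused. Gene symbols are those of the table, and 3320 genes had a blank symbol (43 of those tested). The supplied reference annotation is of an older build than GRCm39 and was used only through gene identifiers, for missing symbols, gene types, transcript length and GC content; 99.6% of the identifiers matched, and no coordinates are given because the builds differ.

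Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter and a 2-group design without covariates, and adjusted by the Benjamini-Hochberg method at 0.05. The filter kept 15218 genes holding 99.8% of the counts, and 27439 genes had no count in any library. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 3 libraries. The SE of a log2 fold change was computed as the size of the fitted coefficient divided by the square root of the F statistic. For genes with few Sham counts the ratio of group totals, corrected for scaled library sizes, has an exact 95% Clopper-Pearson interval; such intervals cover counting error only. Single values per library were compared by a two-sided exact permutation test over the 10 splits of the 6 libraries, which cannot go below p = 0.1, with adjustment over 7 measures.

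The 36 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The named genes were (a) the 10 largest rises and the 10 largest falls among protein-coding genes with an official symbol that passed the test, had a mean of at least 1 CPM and did not overlap between groups, (b) up to 4 members per list with the smallest p among those past the threshold (the 2 most abundant where none passed), and (c) 27 genes of atrial remodelling chosen in advance, of which 25 could be tested, with the results of some not reported here; (d) genes weighed in the closing section were chosen after their values were seen. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 35 lists with at least 3 tested members, and again with an estimated correlation and with fry.

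The alternatives were DESeq2 size factors, library totals without TMM factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, mitochondrial and haemoglobin genes left out, a robust dispersion, a glmTreat test against a 1.5-fold change, the replicate number as a block, and each library left out in turn. Chosen after the data were examined were the removal of trends in GC content and transcript length (splines with 5 degrees of freedom), protein-coding genes alone, and MR library 3 as the sole MR library, because fat cell genes were high in MR libraries 1 and 2. In that last fit the lone MR library is assumed to vary like the others. The removal of GC content and length trends also centred each library on its mean log2 level over genes, beyond the TMM scaling. Library pairs within a group differed by 13.3 to 23 times the sampling noise (chi-square per degree of freedom), so no library was counted as a duplicate.

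The steps were tested on simulated counts for the MR against Sham comparison with the real means, spread and library sizes of 15218 genes. The edgeR test recovered 38% of genes changed 1.5-fold, 80% of those changed 2-fold, 96% of those changed 4-fold and 100% of those changed 8-fold, and called 10 unchanged genes. Both planted lists were called by every set test, and of 30 unchanged lists camera with the preset correlation called 0 and fry 1. The simulated genes varied independently, whereas the real lists had estimated correlations of up to 0.83. These counts therefore do not measure false calls among lists whose genes vary together.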

Results

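Left atrial tissue was profiled by poly(A) RNA sequencing in adult male C57BL/6J mice whose anterior mitral leaflet had been punctured under ultrasound guidance, so that the valve leaked (mitral regurgitation, MR). The control mice (Sham) had a puncture of the cardiac apex with the leaflet left intact. Surgery was at 10 weeks of age, the tissue was taken 2 weeks afterwards, and each group held 3 mice with 1 library each. The comparison asks which transcripts of the left atrium differ while the chamber remodels under regurgitation. Gene counts summed to 20039490, 15008998 and 14718462 in Sham libraries 1 to 3 and to 14313801, 14124407 and 19222343 in MR libraries 1 to 3. At these depths a floor of 3 counts corresponded to between 0.15 and 0.212 CPM on unscaled library totals. Gene levels in CPM are the count as a share of its scaled library total. Spearman correlations across genes were 0.991 to 0.992 within Sham, 0.986 to 0.988 within MR and 0.959 to 0.98 between the groups, and genes are not independent replicates. The first principal component of the 500 most variable genes held 74.4% of their variance and separated the groups.

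Bmp10 (ENSMUSG00000030046), which encodes a secreted growth factor of atrial cardiomyocytes, was nearly undetected in Sham and among the abundant transcripts in MR. The gene also stands in the list of right atrium and sinus node genes that the closing section weighs. It was at 0.21 ± 0.0605 CPM in Sham, from 10 counts in total, and at 3106 ± 241 CPM in MR (SD, n = 3), a log2 fold change of 13.76 ± 0.23 (SE; edgeR adjusted p = 5.1e-10). Cd207, the langerin of dendritic cells and some macrophages, rose by 7.77 on the log2 scale from 5 Sham counts, and Cxcl13, a chemokine that attracts B cells, by 7.67 from 5. Hamp, the iron hormone hepcidin, rose from 2.96 ± 1.64 to 64.5 ± 7.06 CPM (log2 fold change 4.47 ± 0.25, edgeR adjusted p = 1.58e-05). A2m, the protease inhibitor alpha-2-macroglobulin, and Alox8, a lipoxygenase, had 3 counts each in Sham, and their MR to Sham ratios were 240.2 (95% interval 81.9 to 1167) and 69.1 (95% interval 23.3 to 337), intervals that cover counting error only. Arpp21 rose by 4.68 on the log2 scale. Cyp2e1, B3galt2 and Jchain, the joining chain of antibodies, completed the 10 largest rises, but each missed the threshold without Sham library 1 (edgeR adjusted p = 0.0576, 0.0698 and 0.121). B3galt2 also missed it without Sham 2 (0.0517), and Jchain without Sham 2, Sham 3 or MR 2 (0.0909, 0.0771 and 0.0515). Cyp2e1 was at 105, 178 and 3.34 CPM in MR libraries 1 to 3 and at most 3.11 CPM in Sham, and B3galt2 at 6.74, 11.3 and 0.648 CPM in MR and at most 0.506 CPM in Sham. The fat cell genes described below were likewise high in MR libraries 1 and 2 and low in MR library 3. Whether Cyp2e1 and B3galt2 rose with them was not tested. Jchain was at 65.7 CPM in MR library 2 and at 3.99 and 0.898 CPM in MR libraries 1 and 3, and without MR 2 its log2 fold change was 2.49, from 5.79.

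Among the 10 largest falls, Tnni2, the troponin I of fast skeletal muscle, went from 18.9 ± 4.56 to 3.17 ± 2.23 CPM (log2 fold change -2.59 ± 0.38, edgeR adjusted p = 0.00295). Ddit4l (-2.48 ± 0.22), an inhibitor of mTOR signalling, and Ppp1r1b (-2.11 ± 0.28), the phosphatase regulator DARPP-32, fell on the log2 scale, the latter from 113 to 26.2 CPM. Rprm, Vash2, Iyd, Lrrc38 and Lypd8l fell, with log2 fold changes between -2.47 and -2.08, and Nsg2 fell by 2.07, a call that ended without Sham 1 (edgeR adjusted p = 0.0526). Lars2, annotated as the mitochondrial leucyl-tRNA synthetase, fell most (-2.98 ± 0.42), and its level moved with transcripts of ribosomal RNA. The share of counts in mt-Rnr1, mt-Rnr2 and the rRNA-like Gm42418 was 2.87 ± 0.963% in Sham and 0.735 ± 0.139% in MR (SD, n = 3). The two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 can give, and 0.233 after Benjamini-Hochberg adjustment over 7 measures. The value of Lars2 is therefore uncertain.

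**Figure D1:**
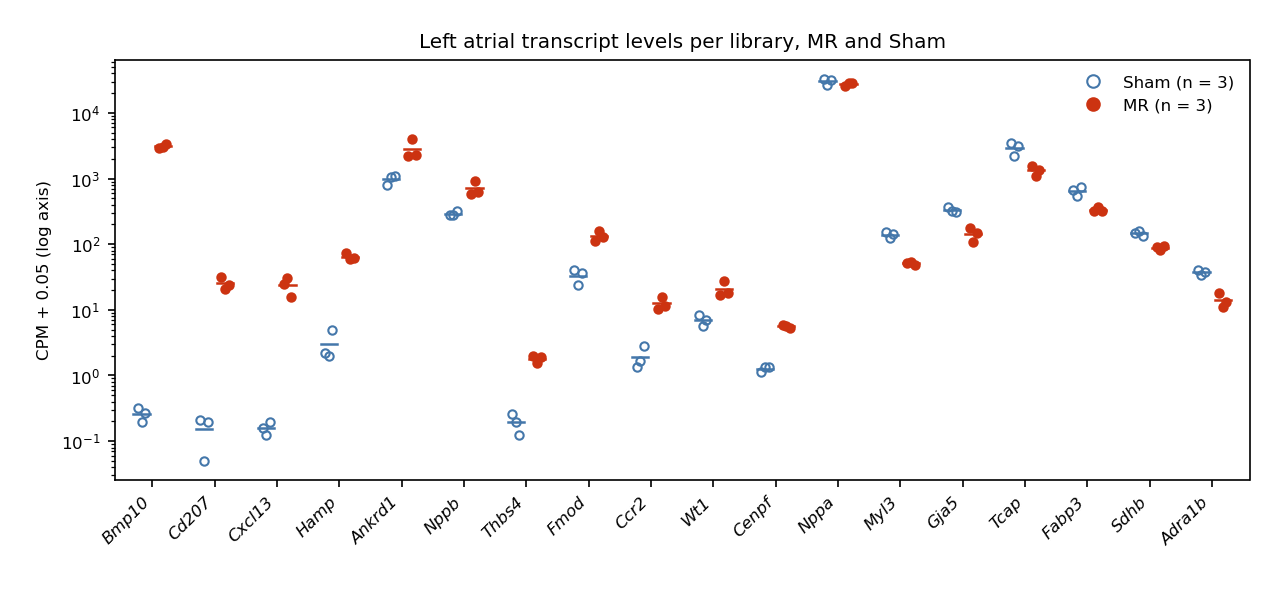
Level of 18 named genes in each library, as CPM plus 0.05 on a log axis, with open circles for the 3 Sham libraries, filled circles for the 3 MR libraries and bars for the group means. Bmp10 lay between 2900 and 3371 CPM in MR and at 0.266 CPM or below in Sham, whereas Nppa overlapped between the groups.

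In all, 3408 of 15218 tested genes (22.4%) changed, 1793 of them higher and 1615 lower in MR (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The change was at least 2-fold for 743 genes, of which 607 were higher and 136 lower. The 3 MR values did not overlap the 3 Sham values for 6369 genes (41.9%), against 10% by chance. Scaled by library totals alone, which shifts the median gene by 0.21 on the log2 scale, the split was 4025 higher and 574 lower. With trends of GC content and transcript length removed it was 1516 higher and 2713 lower. That fit also centred each library on its mean log2 level over genes, so this split cannot be credited to the trends alone. The count was 1583 without Sham library 1, 1897 without Sham library 2, 1941 without MR library 2 and 976 with MR library 3 as the sole MR library.

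Stretch-responsive Ankrd1, a cofactor of muscle gene expression, and Nppb, the precursor of B-type natriuretic peptide, rose in MR. Ankrd1 went from 985 ± 168 to 2808 ± 977 CPM (log2 fold change 1.51 ± 0.23, edgeR adjusted p = 0.00316) and Nppb from 291 ± 22.6 to 716 ± 187 CPM (1.30 ± 0.17, edgeR adjusted p = 0.00189). Nppa, the precursor of atrial natriuretic peptide, was at 30526 ± 3334 CPM in Sham and 27699 ± 1693 CPM in MR, a log2 fold change of -0.14 ± 0.19 that did not pass (edgeR adjusted p = 0.626). Of 18 tested natriuretic peptide and stretch or hypertrophy genes, 3 rose and 5 fell (3 and 8 adjusted over the list alone), with a median log2 fold change of -0.24. The set test camera gave an adjusted p = 0.116 for this list, and an adjusted p = 0.521 with an estimated correlation. Des, the muscle intermediate filament desmin, fell by 0.51 on the log2 scale and the chaperone gene Cryab by 0.52. The call of Cryab ended without Sham 1 or Sham 3 (edgeR adjusted p = 0.061 and 0.0665), and those of both genes ended under scaling by library totals (0.0546 for Des and 0.0713 for Cryab). Myh7, the beta myosin heavy chain, did not pass (log2 fold change -0.64 ± 0.21, edgeR adjusted p = 0.0535), and Acta1 (3, 6 and 8 counts in Sham, 10, 19 and 9 in MR) and Spp1 (1, 0 and 0 counts in Sham, 4, 14 and 6 in MR) had too few counts to be tested. Of the natriuretic and stretch list, 3 changed without Sham 3, 4 without Sham 1 or MR 2 and 5 without Sham 2 or MR 3. Under scaling by library totals 3 rose and 0 fell, with a median log2 fold change of -0.04. There camera called the list of natriuretic peptides and stretch or hypertrophy genes downward against all other genes (adjusted p = 0.0431).

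Matrix and fibroblast genes rose in part. Of 37 tested genes of the non-collagen matrix and its remodelling, 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 fold change of 0.51, and camera gave an adjusted p = 1.47e-05 (adjusted p = 0.466 with an estimated correlation). The matricellular genes Thbs4 (log2 fold change 3.47 ± 0.41) and Comp (0.76 ± 0.12) rose, as did Fmod (fibromodulin, 1.99 ± 0.18), the matrix protease gene Mmp3 (1.79 ± 0.27) and the protease inhibitor gene Timp1 (1.24 ± 0.20). Fmod went from 33.2 ± 8.11 to 132 ± 22.9 CPM (edgeR adjusted p = 0.000382), whereas Thbs4 was low, at 1.74 CPM in MR. For the collagens, 5 of 18 rose and 0 fell (12 and 1 adjusted over the list alone), with camera at an adjusted p = 0.00458 (adjusted p = 0.521 with an estimated correlation). Col16a1 (1.12 ± 0.22) and Col6a3 (1.03 ± 0.23) rose, and so did Col8a2 and Col12a1, whose calls ended without Sham 1 (edgeR adjusted p = 0.057 and 0.0946), that of Col12a1 also without Sham 2 or MR 2 (0.0686 and 0.0707). The main fibrillar collagen genes Col1a1 (0.54 ± 0.22, edgeR adjusted p = 0.0975) and Col3a1 (0.52 ± 0.20, edgeR adjusted p = 0.0917) did not pass.

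Of 15 activated fibroblast and myofibroblast genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone), although 10 of the listed genes also stand in other lists. Camera gave this list an adjusted p = 0.00234, and an adjusted p = 0.516 with an estimated correlation. Acta2, smooth muscle actin, rose from 19.9 ± 3.48 to 41.5 ± 7.6 CPM, and Postn, periostin, from 41.7 ± 5.25 to 80.5 ± 23.2 CPM (edgeR adjusted p = 0.00295 and 0.00779). In the TGF-beta list 6 of 20 rose and 0 fell (9 and 0 adjusted over the list alone). The camera adjusted p was 0.00738 for this list, against an adjusted p = 0.444 with an estimated correlation. Among the members that rose were Smad6 (1.85 ± 0.17) and Smad7 (1.03 ± 0.14), inhibitors of BMP and TGF-beta signalling, and Tgfbi (0.59 ± 0.11) and the receptor gene Tgfbr1 (0.40 ± 0.09) also rose, the last not without Sham 1 or MR 2 (edgeR adjusted p = 0.0576 and 0.0506). Ccn2 (0.50 ± 0.22, edgeR adjusted p = 0.129) and Tgfb2 (0.34 ± 0.15, edgeR adjusted p = 0.143) did not pass. With 1 library left out, between 10 and 18 matrix genes changed. Of the collagens, 3 changed without Sham 1, Sham 2 or MR 2. Of the fibroblast list, 4 changed without Sham 1 and 11 without MR 1, and of the TGF-beta list, 3 changed without Sham 1 or MR 2. Under scaling by library totals 26 matrix, 13 collagen, 14 TGF-beta and 10 fibroblast genes rose. With no filter on low counts 23 matrix, 8 collagen, 11 TGF-beta and 11 fibroblast genes rose, and tested against a 1.5-fold change 4, 0, 1 and 1 did.

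Macrophage and monocyte markers rose as a group: 17 of 22 were higher and 0 lower (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.79 and a camera adjusted p = 6.81e-08 (adjusted p = 0.444 with an estimated correlation). Ccr2, the chemokine receptor of recruited monocytes, rose from 1.88 ± 0.771 to 12.5 ± 2.88 CPM (log2 fold change 2.76 ± 0.27, edgeR adjusted p = 0.000511). Mpeg1 (1.47 ± 0.18), the complement gene C1qb (0.82 ± 0.11), Lyve1 (1.01 ± 0.14), a marker of resident macrophages and lymphatic vessels, and Adgre1 (0.79 ± 0.13), which encodes F4/80, rose too. Inflammatory cytokine, chemokine and inflammasome genes were higher for 10 and lower for 1 of 21 (15 and 2 adjusted over the list alone). In the set test camera the list had an adjusted p = 4.17e-05 (adjusted p = 0.444 with an estimated correlation). Among them the adhesion genes Vcam1 (0.71 ± 0.11) and Icam1 (0.87 ± 0.14) and the inflammasome genes Casp1 (0.97 ± 0.17) and Gsdmd (0.73 ± 0.11) rose. Of 6 tested neutrophil and mast cell markers, 5 rose and 0 fell (5 and 0 adjusted over the list alone), among them the mast cell proteases Cma1 (2.89 ± 0.68), Mcpt4 (2.12 ± 0.50) and Cpa3 and the receptor gene Csf3r (1.12 ± 0.27). By camera this list had an adjusted p = 0.0197, against an adjusted p = 0.466 with an estimated correlation. The lymphocyte genes Lck (1.93 ± 0.46) and Cd79b (2.43 ± 0.69) rose, 2 of 4 tested members with 0 lower (3 and 0 adjusted over the list alone). For these genes together camera gave an adjusted p = 0.0433 (adjusted p = 0.466 with an estimated correlation). These mast cell and lymphocyte calls ended with 1 library left out, those of Lck and Csf3r without Sham 1, Sham 2 or MR 2 (edgeR adjusted p up to 0.0715 and 0.0795). Those of Cd79b and Cpa3 ended without Sham 1, Sham 2, Sham 3 or MR 2 (up to 0.119 and 0.117), that of Cma1 without Sham 1 or Sham 2 (up to 0.0682) and that of Mcpt4 without Sham 2 (0.0552). Without MR 2 the log2 fold change of Cd79b was 1.25. Of 16 type I interferon response genes, 2 rose and 0 fell (1 and 0 adjusted over the list alone), namely Oasl2 (0.83 ± 0.14) and Bst2 (0.41 ± 0.13), the latter not without Sham 1, Sham 2, Sham 3, MR 2 or MR 3 (edgeR adjusted p up to 0.161). Set against all other genes, the list had a camera adjusted p = 0.0358 (adjusted p = 0.591 with an estimated correlation). Of the macrophage list, 11 changed without Sham 1, of the cytokine list, 7 changed without Sham 1, and of the interferon list, 1 changed without Sham 1, Sham 2, MR 2 or MR 3. The camera call of the interferon list ended without Sham 1, Sham 2 or MR 3 (adjusted p = 0.142, 0.144 and 0.202 for the list of type I interferon response genes). Under scaling by library totals 16 cytokine list genes and 7 interferon genes rose, and the camera calls of the interferon, lymphocyte, and neutrophil and mast cell lists ended (adjusted p = 0.0642, 0.208 and 0.0816). With no filter on low counts 10 lymphocyte, 8 neutrophil and mast cell and 4 interferon genes rose, with DESeq2 6 lymphocyte genes and 1 interferon gene, and with limma-voom 1 lymphocyte gene and 3 neutrophil and mast cell genes. Tested against a 1.5-fold change, 4 macrophage markers rose and 0 genes of the other lists of this paragraph. Of the lymphocyte list, 0 changed without Sham 1, Sham 2 or MR 2 and 5 without MR 3, and of the neutrophil and mast cell list, 0 changed without Sham 2, 1 without Sham 1 and 2 without MR 2.

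Of 27 tested cell cycle genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.84 and a camera adjusted p = 3.48e-06 (adjusted p = 0.444 with an estimated correlation). Cenpf, a kinetochore gene of dividing cells, rose from 1.23 ± 0.14 to 5.56 ± 0.298 CPM (log2 fold change 2.18 ± 0.20, edgeR adjusted p = 0.000353), and the replication gene Mcm3 rose by 0.60. Mki67, which encodes the proliferation antigen Ki-67, rose from 4.19 ± 2.28 to 10.8 ± 2.54 CPM (1.40 ± 0.37, edgeR adjusted p = 0.0241), a call that ended without Sham 3 or MR 2 (0.051 and 0.065). Of this list, 2 changed without MR 2 and 3 without Sham 1 or Sham 3, and 14 rose under scaling by library totals.

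Channel and connexin genes of the atrium fell more often than they rose. Of 27 tested, 13 fell and 2 rose (19 and 2 adjusted over the list alone), with a median log2 fold change of -0.50 and a camera adjusted p = 5.13e-05 (adjusted p = 0.444 with an estimated correlation). Gja5, which encodes the atrial gap junction protein connexin 40, fell from 331 ± 29.4 to 145 ± 35.4 CPM (log2 fold change -1.19 ± 0.17, edgeR adjusted p = 0.00225). The potassium channel genes Kcnk3 (TASK-1, -0.92 ± 0.12), Kcnd2 (-0.91 ± 0.16) and Kcnj11 (-0.55 ± 0.11) fell. So did Kcnj3 (-0.53 ± 0.16), of the acetylcholine-gated channel, but this call ended without Sham 1, Sham 2, Sham 3, MR 2 or MR 3 (edgeR adjusted p up to 0.108) and under scaling by library totals (0.117). Kcna5 did not pass (0.11 ± 0.14, edgeR adjusted p = 0.6). Of 26 calcium handling genes, 11 fell and 2 rose (11 and 4 adjusted over the list alone), with a median of -0.16 that came to 0.04 under scaling by library totals. Tested with camera, the members had an adjusted p = 0.0188 together (adjusted p = 0.466 with an estimated correlation). Hrc (-0.83 ± 0.18) and Casq2 (-0.53 ± 0.11), which encode calcium-binding proteins of the sarcoplasmic reticulum, Jph2 (-0.52 ± 0.11) and the calcium channel subunit gene Cacna2d1 (-0.62 ± 0.10) fell. Atp2a2, the calcium pump SERCA2a, was at 13657 ± 813 CPM in Sham and 8293 ± 2222 CPM in MR (-0.72 ± 0.21, edgeR adjusted p = 0.0332), and the release channel gene Ryr2 fell by 0.64 (edgeR adjusted p = 0.0199). The call of Ryr2 ended without any 1 of the Sham libraries (adjusted p up to 0.0666), and that of Atp2a2 without any 1 library other than MR 1 (up to 0.101) and under scaling by library totals (0.0633). Under scaling by library totals 6 channel genes fell and 3 rose, and 6 calcium handling genes fell and 5 rose. Tested against a 1.5-fold change, 1 channel gene and 0 calcium handling genes fell. Of the channel list, 5 changed without Sham 3, 6 without Sham 2, 7 without Sham 1, 8 without MR 2 and 9 without MR 3, and of the calcium list, 5 changed without Sham 1 and 6 without Sham 2 or Sham 3.

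Among 19 tested transcription factors of atrial identity and rhythm, a list that also holds Bmp10, 5 rose and 5 fell (5 and 6 adjusted over the list alone), with a median of 0.04 and a mean of 0.85 (camera adjusted p = 0.729, adjusted p = 0.773 with an estimated correlation). Prrx1 fell by 0.54 on the log2 scale. Gata5 rose from 1.77 ± 0.528 to 8.54 ± 2.32 CPM (log2 fold change 2.23 ± 0.26, edgeR adjusted p = 0.00126). Of 15 atrial cardiomyocyte markers, 2 rose and 7 fell (2 and 8 adjusted over the list alone). Their median was -0.34, whereas their mean of 0.74 was positive because it includes Bmp10; camera gave a downward adjusted p = 0.321 (adjusted p = 0.638 with an estimated correlation) and fry an upward adjusted p = 0.0125. Stard10 fell by 0.72, and the atrial myosin light chain genes Myl4 (-0.70 ± 0.17) and Myl7 (-0.56 ± 0.17) and the calcium pump regulator Sln (-0.49 ± 0.12) fell. The calls of Myl4 and Sln ended without Sham 1, Sham 3 or MR 3 (edgeR adjusted p up to 0.0797 and 0.0728) and that of Myl7 without Sham 1, Sham 3, MR 2 or MR 3 (up to 0.121). Those of Myl7 and Sln also ended under scaling by library totals (edgeR adjusted p = 0.11 and 0.0856), where 3 atrial markers rose and 2 fell. Of the atrial markers, 2 changed without Sham 1 or MR 3, 4 without Sham 3 or MR 2 and 5 without Sham 2.

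Many genes of energy metabolism and part of the sarcomere genes fell in MR. Of 47 nuclear-encoded genes of oxidative phosphorylation, 41 fell and 0 rose (45 and 0 adjusted over the list alone), with a median log2 fold change of -0.56 and a camera adjusted p = 3.35e-17 (adjusted p = 0.444 with an estimated correlation). Sdhb of complex II fell from 146 ± 11 to 88.5 ± 6.28 CPM (-0.73 ± 0.10, edgeR adjusted p = 0.00211), and the complex I genes Ndufb10 (-0.88 ± 0.13), Ndufb8 (-0.77 ± 0.11) and Ndufa9 (-0.66 ± 0.11) fell. Of 32 genes of fatty acid uptake and oxidation, 20 fell and 0 rose (22 and 1 adjusted over the list alone; median -0.54). Camera gave this list an adjusted p = 3.48e-06, and an adjusted p = 0.466 with an estimated correlation. The fatty acid binding protein gene Fabp3 went from 651 ± 99.2 to 335 ± 24.1 CPM (-0.96 ± 0.13, edgeR adjusted p = 0.00204), and Acsl1 (-0.70 ± 0.13), Eci1 (-0.68 ± 0.13) and the carnitine carrier gene Slc25a20 (-0.58 ± 0.10) fell. Cpt1b (0.25 ± 0.23, edgeR adjusted p = 0.457) and Pdk4 (-0.04 ± 0.19, edgeR adjusted p = 0.906) did not pass. For glycolysis and glucose use, 11 of 23 fell and 3 rose (12 and 4 adjusted over the list alone). The camera adjusted p was 0.00743 for this list, against an adjusted p = 0.444 with an estimated correlation. The muscle enolase gene Eno3 (-0.97 ± 0.16), Pgam2 (-0.74 ± 0.10) and Ldhb (-0.60 ± 0.12) fell, and the lactate exporter gene Slc16a3 rose by 1.37.

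Of 22 sarcomere genes, 11 fell and 0 rose (15 and 0 adjusted over the list alone), with a median log2 fold change of -0.47 and a camera adjusted p = 2.18e-07 (adjusted p = 0.444 with an estimated correlation). The titin cap gene Tcap fell from 2931 ± 657 to 1334 ± 238 CPM (-1.14 ± 0.19, edgeR adjusted p = 0.00502), and Myoz2 (-0.87 ± 0.12), Myom1 (-0.51 ± 0.11) and the cardiac troponin I gene Tnni3 (-0.75 ± 0.16) fell, the last not without Sham 1 (edgeR adjusted p = 0.0521). Myh6, the main atrial myosin heavy chain, did not pass (-0.42 ± 0.22, edgeR adjusted p = 0.194). Markers more abundant in ventricular cardiomyocytes fell for 5 and rose for 1 of 10 (7 and 2 adjusted over the list alone), with Myl3 going from 140.0 ± 15 to 51.1 ± 2.57 CPM (-1.46 ± 0.11, edgeR adjusted p = 9.75e-05). In the set test camera the list had an adjusted p = 0.0197 (adjusted p = 0.444 with an estimated correlation). The mRNAs of mitochondrial DNA made up 20.7 ± 1.4% of counts in Sham and 18.6 ± 1.42% in MR (SD, n = 3; two-sided exact permutation p = 0.2, 0.35 after adjustment). Of these 13, 2 fell and 0 rose (1 and 0 adjusted over the list alone), namely mt-Co3 and mt-Atp8. By camera this list had an adjusted p = 0.00203, against an adjusted p = 0.466 with an estimated correlation. The call of mt-Co3 ended without Sham 1, Sham 2, Sham 3, MR 1 or MR 3 (edgeR adjusted p up to 0.138) and that of mt-Atp8 without Sham 1, Sham 2 or MR 2 (up to 0.0874), and mt-Atp8 overlaps mt-Atp6, so its count is uncertain. Of these transcripts, 0 changed without Sham 1 or Sham 2 and 1 without MR 1, MR 2 or MR 3. These falls stood beside the lower share of ribosomal RNA in MR. Of the oxidative phosphorylation list, 24 changed without Sham 1, of the fatty acid list, 9 changed without Sham 1, and of the glycolysis list, 7 changed without Sham 1, 8 without Sham 2 and 9 without Sham 3 or MR 2. Of the sarcomere list, 3 changed without Sham 1, 6 without Sham 3 or MR 3 and 7 without MR 2, and of the ventricular list, 2 changed without Sham 3 and 3 without Sham 1 or Sham 2. Under scaling by library totals 28 oxidative phosphorylation, 11 fatty acid and 5 sarcomere genes fell, and 3 fatty acid genes rose, while 5 glycolysis genes fell and 5 rose and 2 ventricular markers fell and 2 rose. Of the mitochondrial transcripts 1 fell under that scaling, 8 fell with DESeq2, 6 with no filter on low counts and 1 with a robust dispersion or with GC and length trends removed. Tested against a 1.5-fold change, 0 oxidative phosphorylation, fatty acid, glycolysis, sarcomere and mitochondrial genes changed. With MR library 3 as the sole MR library 11 oxidative phosphorylation, 8 fatty acid, 4 glycolysis and 4 sarcomere genes fell and 1 glycolysis gene rose.

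**Figure D2:**
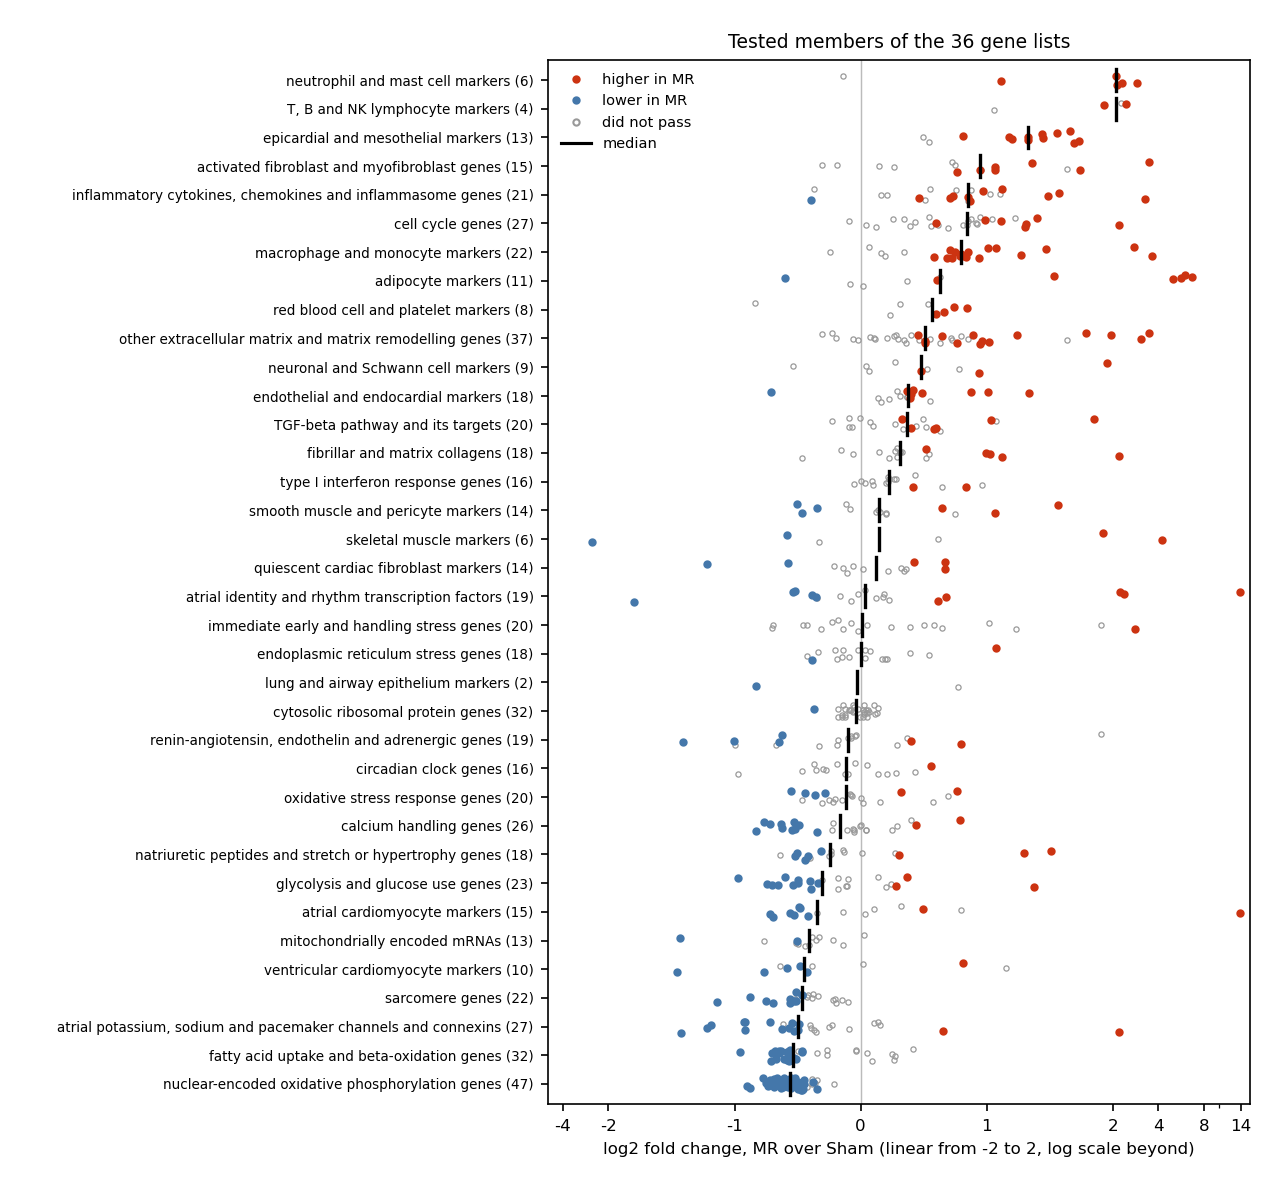
Log2 fold change of MR over Sham for each tested member of the 36 gene lists, with the number tested in brackets; the axis is linear from -2 to 2 and logarithmic beyond. Red and blue points passed the test as higher and lower, open points did not pass, and black bars are list medians, which run from -0.56 for oxidative phosphorylation to 2.11 for neutrophil and mast cell markers.

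Markers of other cell types of the heart moved to different extents. Epicardial and mesothelial markers rose for 11 and fell for 0 of 13 (13 and 0 adjusted over the list alone), with a median log2 fold change of 1.33 and a camera adjusted p = 1.7e-07 (adjusted p = 0.444 with an estimated correlation). Wt1, the transcription factor of epicardial cells, went from 6.96 ± 1.38 to 20.7 ± 5.66 CPM (1.56 ± 0.21, edgeR adjusted p = 0.00204), and Lrrn4 (1.73 ± 0.24), Bnc1 (1.69 ± 0.25) and the retinoic acid enzyme gene Aldh1a2 (1.18 ± 0.17) rose. Of 18 endothelial and endocardial markers, 8 rose and 1 fell (12 and 1 adjusted over the list alone): Vwf, von Willebrand factor, rose by 1.33 and Esam by 0.49, and Prox1 fell by 0.71. For these genes together camera gave an adjusted p = 0.000284 (adjusted p = 0.444 with an estimated correlation). Quiescent fibroblast markers rose for 3 and fell for 2 of 14 (3 and 2 adjusted over the list alone), with Pcolce up by 0.67 and Pi16 down (-0.58 ± 0.12). Set against all other genes, the list had a camera adjusted p = 0.601 (adjusted p = 0.659 with an estimated correlation). Smooth muscle and pericyte markers were higher for 3 and lower for 3 of 14 (4 and 3 adjusted over the list alone), and Cnn1 rose by 1.57. Tested with camera, the members had an adjusted p = 0.523 together (adjusted p = 0.773 with an estimated correlation). Of 9 neuronal and Schwann cell markers, 3 rose and 0 fell (3 and 0 adjusted over the list alone), with Dbh, the enzyme of noradrenaline synthesis, going from 3.61 ± 0.958 to 13.9 ± 1.17 CPM (1.95 ± 0.18, edgeR adjusted p = 0.000422). Camera gave this list an adjusted p = 0.0449, and an adjusted p = 0.466 with an estimated correlation. With 1 library left out, 11 or 12 epicardial markers changed. Of the endothelial list, 4 changed without Sham 1, of the quiescent fibroblast list, 2 changed without Sham 1, Sham 2 or Sham 3 and 3 without MR 3, of the smooth muscle list, 3 changed without Sham 1 or Sham 2, and of the neuronal list, 1 changed without Sham 1. The camera call of the list of neuronal and Schwann cell markers ended without MR 1 (adjusted p = 0.0907), under scaling by library totals (0.137) and with the replicate number as a block (0.0669). Under scaling by library totals 15 endothelial markers rose and 1 fell, 6 smooth muscle and pericyte markers rose and 0 fell, and 5 quiescent fibroblast markers rose and 2 fell.

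Adipocyte markers separated the MR libraries. Of 11 tested, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The camera adjusted p was 0.0869 for this list, against an adjusted p = 0.638 with an estimated correlation. Cfd, the fat cell protease adipsin, was at 206 and 402 CPM in MR libraries 1 and 2 and at 2.05 CPM in MR library 3, against at most 5.06 CPM in Sham, and Adipoq and Cidec had the same distribution. With MR library 3 as the sole MR library none of these 3 genes was called (log2 fold changes -0.02, -0.74 and -0.30), and their calls ended without Sham 1 or Sham 2 (edgeR adjusted p up to 0.0715, 0.0922 and 0.0793). Of the adipocyte list, 0 changed without Sham 1, 1 without Sham 2 and 3 without Sham 3, and all 6 rises ended with limma-voom and with a robust dispersion, where 0 rose and 1 fell, whereas 10 rose and 1 fell with no filter on low counts. Camera called the list of adipocyte markers without Sham 1, Sham 3 or MR 3 (adjusted p = 0.0438, 0.028 and 6.56e-06). Haemoglobin genes took 0.0275 ± 0.00317% of counts in Sham and 0.0514 ± 0.00624% in MR (SD, n = 3; two-sided exact permutation p = 0.1, 0.233 after adjustment). Of 8 red blood cell and platelet markers, 4 rose and 0 fell (6 and 0 adjusted over the list alone), all 4 of them haemoglobin genes such as Hba-a2 (0.84 ± 0.09). In the set test camera the list had an adjusted p = 0.00629 (adjusted p = 0.444 with an estimated correlation). Near-identical haemoglobin copies share reads, so their single values are uncertain. The call of Hbb-bt ended without Sham 3 (edgeR adjusted p = 0.0509) and that of Hbb-bs without Sham 1, Sham 2, Sham 3, MR 1 or MR 3 (up to 0.1), and of the list 2 changed without Sham 3. Skeletal muscle markers went both ways, with 2 of 6 higher and 2 lower (3 and 2 adjusted over the list alone). By camera this list had an adjusted p = 0.561, against an adjusted p = 0.638 with an estimated correlation. Actn3 (1.93 ± 0.27) and Pvalb (4.24 ± 0.60, 4 Sham counts) rose, and Tnni2 and Ckm (-0.58 ± 0.15) fell, Ckm not without Sham 1 or Sham 3 (edgeR adjusted p = 0.07 and 0.0715). Of 2 tested lung and airway markers, too few for a set test, Hopx, which the heart also expresses, fell by 0.83 and the other did not pass (1 lower and 0 higher adjusted over the list alone). In this list 1 gene rose and 1 fell without MR 1, with DESeq2 and with no filter on low counts.

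**Figure D3:**
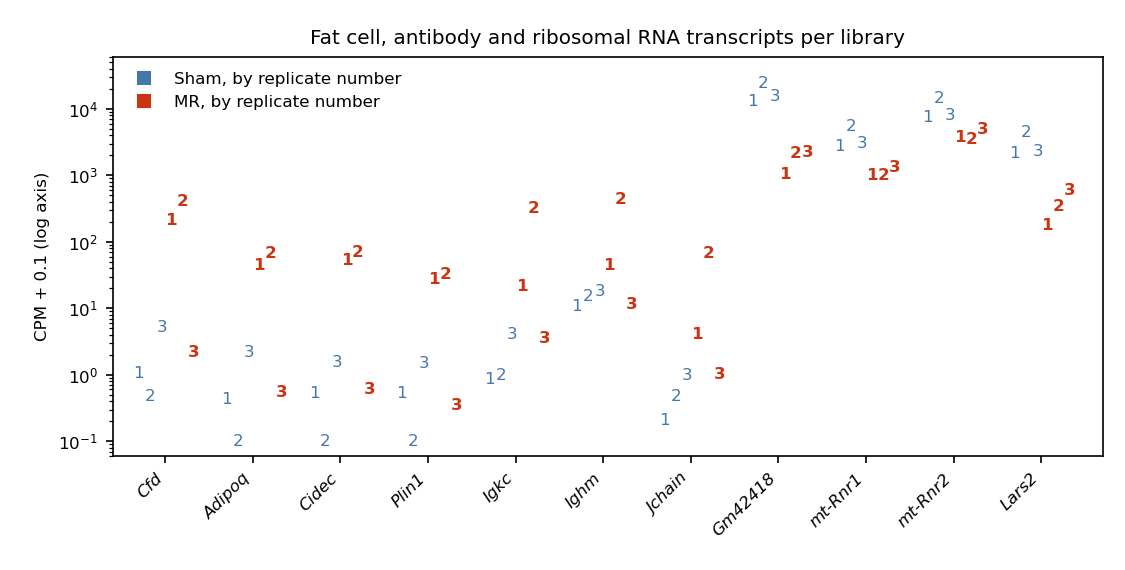
Level of fat cell genes (Cfd, Adipoq, Cidec, Plin1), antibody genes (Igkc, Ighm, Jchain), ribosomal RNA transcripts (Gm42418, mt-Rnr1, mt-Rnr2) and Lars2 in each library, as CPM plus 0.1 on a log axis, chosen after their values were seen. Each digit is the replicate number of 1 library, blue for Sham and bold red for MR; MR library 3 lies with the Sham libraries for the fat cell genes.

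Genes of the renin-angiotensin, endothelin and adrenergic systems fell for 4 and rose for 2 of 19 (5 and 3 adjusted over the list alone). For these genes together camera gave an adjusted p = 0.208 (adjusted p = 0.494 with an estimated correlation). The alpha-1B adrenergic receptor gene Adra1b fell from 37.3 ± 3.49 to 14 ± 3.68 CPM (-1.41 ± 0.16, edgeR adjusted p = 0.00122), the angiotensin receptor gene Agtr1a (-1.01 ± 0.21) and the beta-1 receptor gene Adrb1 (-0.64 ± 0.15) fell, and Ece1, the endothelin-converting enzyme, rose by 0.80. Oxidative stress genes rose for 2 and fell for 4 of 20 (2 and 4 adjusted over the list alone), with the mitochondrial superoxide dismutase gene Sod2 down (-0.55 ± 0.12). Set against all other genes, the list had a camera adjusted p = 0.208 (adjusted p = 0.564 with an estimated correlation). Of 18 endoplasmic reticulum stress genes, 1 rose (Asns, 1.08 ± 0.25) and 1 fell (Hspa5, -0.39 ± 0.12), with 1 and 0 adjusted over the list alone and a camera adjusted p = 0.835 (adjusted p = 0.893 with an estimated correlation). The call of Asns ended without Sham 1 (edgeR adjusted p = 0.0644), and that of Hspa5 ended without any 1 library (up to 0.157). Immediate early genes rose for 1 and fell for 0 of 20 (0 and 0 adjusted over the list alone), the riser being Egr2, which missed the threshold without Sham 1, Sham 2, Sham 3 or MR 3 (edgeR adjusted p up to 0.154). Tested with camera, the members had an adjusted p = 0.888 together (adjusted p = 0.966 with an estimated correlation). Clock genes rose for 1 (Per2) and fell for 0 of 16 (0 and 0 adjusted over the list alone). Camera gave this list an adjusted p = 0.601, and an adjusted p = 0.783 with an estimated correlation. Ribosomal protein genes rose for 0 and fell for 1 (Rps2) of 32 (0 and 0 adjusted over the list alone). The camera adjusted p was 0.523 for this list, against an adjusted p = 0.893 with an estimated correlation. The Per2 call ended without Sham 1, Sham 2, MR 1, MR 2 or MR 3 (edgeR adjusted p up to 0.104) and the Rps2 call without Sham 1, Sham 2, Sham 3, MR 1 or MR 2 (up to 0.0927). Of the endoplasmic reticulum list, 0 changed without Sham 1 and 1 without Sham 2, Sham 3, MR 2 or MR 3, and of the oxidative stress list, 1 changed without Sham 1, 2 without Sham 2 or Sham 3 and 3 without MR 2 or MR 3. Of the immediate early list, 0 changed without Sham 1, 2 without MR 2 or MR 3 and 5 without MR 1, of the clock list, 0 changed without Sham 1, MR 2 or MR 3 and 2 without Sham 3, and of the ribosomal protein list, 0 changed without Sham 1, Sham 2, Sham 3, MR 1 or MR 2. Under scaling by library totals 5 endoplasmic reticulum stress genes, 3 immediate early genes, 4 clock genes and 1 ribosomal protein gene rose and 0 genes of these lists fell, 3 oxidative stress genes rose and 1 fell, and 5 genes of the receptor list rose and 3 fell. With no filter on low counts 8 immediate early genes rose and 5 fell, 2 clock genes rose and 3 fell, and 2 endoplasmic reticulum stress genes rose and 3 fell. With the replicate number as a block 3 immediate early genes rose and 2 fell, 2 clock genes rose and 0 ribosomal protein genes changed. With DESeq2, limma-voom or a robust dispersion 0 immediate early genes changed, whereas 5 rose with MR library 3 as the sole MR library, and the 2 called without MR 3 were lower. Scaled by library totals, the list medians changed sign from -0.12 to 0.09 for oxidative stress, from -0.10 to 0.10 for the receptor list, from -0.11 to 0.09 for clock genes and from -0.04 to 0.17 for ribosomal proteins.

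Over the 35 lists with enough tested members, camera with a preset correlation of 0.01 called 14 upward and 8 downward. None of these 22 calls held with an estimated correlation, where 0 lists passed camera after adjustment (lowest adjusted p = 0.444) and 2 were below 0.05 unadjusted. The test fry, which asks whether the members of a list move on balance one way, called 20 lists, and its mixed test for change in either direction called 30.

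The authors' deposited table holds their own MR against Sham comparison for 19541 genes with an adjusted p-value, of which 2348 were called higher and 2859 lower at 0.05. Of the 15214 genes in both that comparison and the edgeR test, 3139 were called by both, all in the same direction, 268 by edgeR alone and 1765 in the authors' deposited table alone. The log2 fold changes correlated with r = 0.954 across genes, which are not independent replicates. Several abundant atrial genes differed in size: in the authors' deposited table Myl7 had a log2 fold change of -0.03 (adjusted p = 0.75), Myl4 of -0.05 (0.635) and Sln of -0.03 (0.772), whereas DESeq2 refitted to the 6 count columns gave -0.57, -0.71 and -0.50 for these genes. Bmp10 had 13.64 in the authors' deposited table.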

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

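The removal of GC content and length trends, the protein-coding set and the fits with MR library 3 as the sole MR library were chosen after the data were seen. The alternatives for normalized values were not applied, since counts were held. The count of 3408 changed genes lay between 3085 (replicate number as a block) and 4599 (library totals) under the other scalings, filters, tools and gene sets, and 2367 of the 3408 were also called under library totals. With 1 library left out it lay between 1583, without Sham 1, and 3453, without MR 1, and with MR library 3 alone it was 976. The 743 changes of at least 2-fold came to 1242 with no filter on low counts, where 28032 genes were tested, and to 250 when tested against 1.5-fold. They came to between 488 (without Sham 1) and 932 (without MR 1) with 1 library left out and to 379 with MR library 3 alone. The 278 calls of list members came to between 142 (without Sham 1) and 304 (without MR 1) with 1 library left out, to 129 with MR library 3 alone and to between 262 (limma-voom) and 380 (no filter) under the other alternatives run. Camera called 22 lists, of which 0 passed with an estimated correlation, 17 with fry, 18 under library totals and 21 or 22 under DESeq2 size factors, the block and each library left out. For the changes of this paragraph the cause was not tested. The first principal component held 68.1% of the variance over 2000 genes.

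The list of atrial cardiomyocyte markers was called upward by fry (adjusted p = 0.0125). Its mean log2 fold change of 0.74 includes Bmp10, whereas its median was -0.34, and fry without Bmp10 was not run. With MR library 3 alone the log2 fold changes of Cfd, Cidec and Adipoq were -0.0231, -0.30 and -0.74, and the cause of these values was not tested. Of 151 named genes, 141 were called, and 93 of these passed in each of the 6 fits with 1 library left out. The number below the threshold was highest, at 44, without Sham 1 and lowest, at 6, without MR 1. Under library totals 14 named genes were no longer called, among them Des, Cryab, Hspa5, Ucp2, Prdx1, Gyg1, Ckm, Sln, mt-Co3, Rps2, Atp2a2, Myl7 and Kcnj3. With limma-voom 12 were not called, among them Cyp2e1, Jchain, B3galt2, Cfd, Cidec and Adipoq. Col1a1 and Col3a1 were called higher under library totals, with no filter and with the block. Depth limits the genes with few counts, for which 3 counts in a library correspond to up to 0.212 CPM on unscaled library totals. Changes of 1.5-fold were recovered for 38% of simulated genes.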

Other observations

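The gene lists of this part, the genes named in it, the right atrium test, the test of unscaled Bmp10 counts, the test of the second fat list and the test of the gap between cell type lists were chosen only after the results were seen. Complement genes, which mark and clear cells and debris, rose for 10 and fell for 0 of 14 tested (11 and 0 adjusted over the list alone). The camera adjusted p over the 8 added lists was 2.2e-05 (adjusted p = 0.139 with an estimated correlation). C3, the central component, went from 489 ± 51.1 to 1240 ± 154 CPM (SD, n = 3; log2 fold change 1.34 ± 0.13, edgeR adjusted p = 0.000531), and C4b (1.76 ± 0.19) and Cfi (2.89 ± 0.67) rose too, Cfi not without Sham 2 (edgeR adjusted p = 0.0566). Genes of MHC class II and antigen presentation rose for 9 and fell for 0 of 12 (10 and 0 adjusted over the list alone), with H2-Aa going from 27.8 ± 11.9 to 95.8 ± 23.1 CPM and the invariant chain gene Cd74 from 29.5 ± 14.1 to 92.1 ± 17.4 CPM. In the set test camera the list had an adjusted p = 5.92e-05 (adjusted p = 0.251 with an estimated correlation). Of 8 immunoglobulin and plasma cell genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone). By camera this list had an adjusted p = 0.0231, against an adjusted p = 0.298 with an estimated correlation. Igkc, the kappa light chain, was at 20.9, 312 and 3.39 CPM in MR libraries 1 to 3 and at 0.746, 0.876 and 3.98 CPM in Sham libraries 1 to 3, so MR library 2 held most of it. Its log2 fold change fell from 5.97 to 2.74 without MR 2, and its call ended without Sham 1, Sham 2 or Sham 3 (edgeR adjusted p up to 0.0991). Of the immunoglobulin list 0 changed without Sham 2, 1 without Sham 1 or Sham 3 and 2 without MR 2, and of the MHC class II list 5 changed without Sham 1.

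Target genes of BMP signalling rose for 11 and fell for 0 of 15 (11 and 0 adjusted over the list alone). For these genes together camera gave an adjusted p = 1.04e-05 (adjusted p = 0.139 with an estimated correlation). Besides Smad6 and Smad7, which also stand in the TGF-beta list, Id1 (log2 fold change 0.70 ± 0.09), Id2 (1.11 ± 0.19) and Id3 (1.00 ± 0.17), transcriptional inhibitors induced by BMP receptors, rose. IGF axis genes rose for 8 and fell for 1 of 14 (9 and 1 adjusted over the list alone). Set against all other genes, the list had a camera adjusted p = 0.00152 (adjusted p = 0.139 with an estimated correlation). The binding protein gene Igfbp5 went from 494 ± 32.8 to 1458 ± 206 CPM and Igfbp3 from 17.4 ± 2.33 to 112 ± 34.3 CPM (SD, n = 3; edgeR adjusted p = 0.000226 and 0.00013). Fast skeletal muscle genes went both ways, with 3 of 12 higher and 6 lower (4 and 6 adjusted over the list alone). Tested with camera, the members had an adjusted p = 0.152 together (adjusted p = 0.274 with an estimated correlation). Atp2a1, the fast muscle calcium pump, fell from 28.3 ± 3.34 to 8.17 ± 4.19 CPM (-1.79 ± 0.28). Of the IGF axis list 5 changed without Sham 2.

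Alongside the rise of Bmp10, Shox2, a transcription factor of the sinus node, and Hcn4, the pacemaker channel, were higher in MR (log2 fold changes 2.37 ± 0.38 and 2.20 ± 0.54). Hcn4 was at 22.3, 10.3 and 3.59 CPM in MR libraries 1 to 3, its log2 fold change was 1.38 without MR 1, and its call ended without Sham 1, Sham 2 or Sham 3 (edgeR adjusted p up to 0.088). The tables argue against normalization for Bmp10, since before any scaling its lowest MR count was 44344 and its highest Sham count 5, a gap of 13.11 on the log2 scale where the library totals spanned 0.50. Right atrial or sinus node tissue in the MR libraries was tested with a list of 20 genes of these tissues, 18 of them tested, of which 7 are not informative because their values had been seen when the list was written. Those 7 were Bmp10, Shox2, Hcn4, Hamp, Ryr3 (log2 fold change 3.69 ± 0.22), Cacna2d2 (3.08 ± 0.26) and Igfbp5, and all of them rose. Of the other 11, 4 rose and 0 fell, against 11.8% of all tested genes that rose, but fewer than such tissue was predicted to raise. Tissue of the right atrium or sinus node therefore cannot be told apart from regulation within the left atrium under regurgitation, which was not tested and stays open.

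Of 154 genes in the sarcomere, channel, calcium handling, fatty acid and oxidative phosphorylation lists, 96 fell and 4 rose, with a median log2 fold change of -0.52. With trends of GC content and transcript length removed, the median was -0.55 (95% bootstrap interval -0.59 to -0.51) and 111 genes fell, so the fall itself was not reduced. That fit also centred each library on its mean log2 level over genes. The calls over all tested genes moved downward in it, to 1516 higher and 2713 lower, which the trends alone need not have caused. How much of the fall relative to other genes remained is therefore not known, and a bias of GC content or length stays open. A lower share of cardiomyocyte RNA stays open as a cause of all or part of the fall. The medians of the quiescent fibroblast, endothelial, smooth muscle and epicardial lists lay up to 1.21 apart (permutation p = 8e-05 over 59 genes). The epicardial list set this gap with a median of 1.33, but uneven gains of other cell types would also set the medians apart. The permutation treats genes as independent, although the epicardial genes vary together (estimated correlation 0.83). It does not cover the spread between mice, so the test cannot decide this. Less residual ribosomal RNA in the MR libraries stays open, as the slope within groups predicted a change of 0.14 (95% interval -0.93 to 1.21) where -0.43 was observed. The small nuclear RNAs Rn7sk (-3.75 ± 0.22) and Gm22513 (-4.52 ± 0.19) were also lower in every MR library than in every Sham library. So were the small RNAs Rny1 (-3.89 ± 0.43) and Rny3 (-3.79 ± 0.60), which had few counts. The labels name no batch. A difference in library preparation between the groups was therefore not tested and cannot be told apart from MR, for these lists or for the other calls. Regulation in the cardiomyocytes under regurgitation was not tested and stays open.

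Fat cell genes were high in MR libraries 1 and 2 and low in MR library 3 and in Sham: Car3, an abundant fat cell enzyme, was at 249, 394 and 2.34 CPM in MR and at most 6.65 CPM in Sham (not called without Sham 1 or Sham 2, edgeR adjusted p up to 0.0785). In a second list of 20 fat genes, 12 of them tested, 10 had their 2 highest values in those libraries, against 13.3% of all tested genes, but genes of 1 cell type vary together (estimated correlation 0.59). Of that list 6 rose and 0 fell, against 15 without MR 3, when more of the list was tested, 3 without Sham 2 or Sham 3, 2 without MR 2 and 1 without Sham 1 (8 and 0 adjusted over the list alone). Camera gave this list an adjusted p = 0.0023, and an adjusted p = 0.298 with an estimated correlation. Camera compared all MR with all Sham libraries, and a rise in MR libraries 1 and 2 alone itself raises the estimated correlation. The test therefore could not decide on RNA of fat cells in these libraries. The values show that most tested genes of the second fat list were highest in MR libraries 1 and 2. Whether fat cells brought this RNA stays open, and no biological explanation was tested.

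The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3408 changed genes with edgeR and is the 1 split with as many. The highest of the others gave 0, with up to 727 genes at an unadjusted p under 0.05. Every other split mixes Sham and MR libraries, so any group difference, whatever its cause, widens its spread and lowers its count. The splits therefore cannot tell MR from another difference between the groups.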
